A study of Mus musculus with 15 samples.

How the data were processed

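Total RNA from mouse embryonic stem (ES) cells was measured on Affymetrix MGU74A arrays, per the labels, on which a set of short probes (a probe set) reads each transcript. The 15 arrays cover 3 cell lines and 5 time points of stimulation with fetal bovine serum (FBS), with 1 array for each line and time. The lines are the wild-type line E14, an Srf-null line (E100-/-) and its rescue line (E100-/- rescue). The labels do not say how the rescue was made. Groups came from the sample titles, and 0 columns of the table stayed without a sample.

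The deposited table holds intensity values on a linear scale for 12654 probe sets, of which 66 are array controls. The software, background correction and scaling that the authors used are not given in the sources used here. On each array, 24.9% to 41.6% of values were 0 or negative, so a background or mismatch signal had been subtracted before deposit. The 2% trimmed means of the arrays differed up to 4.10-fold, which exceeded the tolerance of 10% set for treating the table as already scaled. The values were therefore quantile-normalized between arrays. Values under the 40th percentile of all normalized values (84.98, log2 6.41) were set to that floor, and log2 was taken. Changes of transcripts at the floor in a group are lower limits. Probe sets above the floor on at least 2 of 15 arrays were tested, which left 9558 probe sets without controls.

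Probe sets were named from the platform annotation, with symbols updated through the gene identifiers for 10279 probe sets. One symbol was given for 10298 probe sets and several for 363, and 1993 were not listed there. Only probe sets with 1 symbol were named. For lists, each gene was read by its probe set with the highest mean, which gave 6764 genes. Single genes were tested over the 9558 probe sets. Members of lists were counted in a second fit over the 6764 genes, so an adjusted p near the threshold can differ between both fits.

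Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and a call was a Benjamini-Hochberg adjusted p under 0.05. Lines were compared in an additive model of line and time with 8 residual degrees of freedom, where the time points of a line stood for its replicates. A call of Srf-null against both other lines, for members of lists too, also needed the same direction against each of them. Serum responses were compared between phases of each line, baseline (0 and 10 min), early (30 and 60 min) and late (180 min), with 6 residual degrees of freedom. Each line was a single culture series as far as the labels say, so p-values measure the spread over time points and not between independently made lines. The number of arrays limits the precision.

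The grouping, the models, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Named genes were Srf; the 8 largest called changes in each direction per line comparison with 1 direction at all time points; the 12 largest rises and 6 largest falls of the mean early response and 6 of each for the late response; the 8 largest called differences of response in each direction; up to 4 members of a list by p; and a fixed set (Egr1, Fos, Fosb, Junb, Ccn1, Vcl, Actb, Actg1, Acta2, Tagln, Zyx, Tpm1, Fhl2, Bcl2 and Myc). Where a count was 5 or fewer, its other genes were named too, after their values had been seen, as were Krt8, Id1, Dusp1 and Eif2s3y where described. Among the largest called changes, a gene with several probe sets was named by the eligible one with the largest change. The probe set of a gene can therefore differ between comparisons.

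The 21 lists were immediate-early genes, actin cytoskeleton genes controlled by SRF and its MRTF cofactors, apoptosis regulators, extracellular matrix and adhesion, G1 and S phase, G2 and mitosis, cholesterol synthesis, ribosomal proteins, heat shock and unfolded protein, interferon response, BMP and TGF-beta targets, hypoxia and glycolysis, p53 targets, imprinted genes, X-inactivation and Y-linked genes as a label check, pluripotency, primitive and visceral endoderm, mesoderm and primitive streak, ectoderm and neural, trophoblast, and fibroblast feeder genes. They were tested with camera at a preset correlation of 0.01, again with the correlation estimated for each list, and with fry, with adjustment over all lists and planned comparisons (231 tests). Single arrays were compared with the first array of their line by the list median and its percentile among 10000 random lists matched on signal.

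Several choices followed after results had been seen. First, the arrays labelled wild-type 0 min and rescue 0 min were doubted, and counts were made without them. The planned setting without all 0 min arrays was then placed beside the 15-array result for the line comparisons, after the counts of all 3 settings had been seen. Its 84 list tests were adjusted together. Because the arrays were doubted on these same values, more calls without them are not independent evidence of a line difference. Second, 60 and 180 min were compared with 10 and 30 min in a model without 0 min arrays, which also has 6 residual degrees of freedom. Later, 2 technical splits of the arrays were added as terms, the 18S split after random regroupings of the arrays with many calls had been seen to follow it. One parts arrays by whether more than 35% of values were 0 or negative, and the other by whether the 18S ribosomal RNA control probe set was above 10000 before normalization.

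The fits were tested on simulated data of 9558 probe sets. Noise was drawn independently for each probe set and array, with the residual spread of the line model. The simulation held no shared array effects, technical splits or doubted arrays, so its recovery and false calls need not hold for the real data. For Srf-null against both lines, 32% of changes of log2 size 1 and 67% of size 2 were recovered, with 8 false calls among 107. Without 0 min arrays the shares were 25% and 58%, with 5 false calls among 88. For the mean early response 35% and 63% were recovered, and for 60 and 180 against 10 and 30 min 28% and 64%. For the difference in early response between lines the shares were 0% and 14%. Other settings covered scaling to a common median or trimmed mean, other floors and filters, the trend, the time term, the baseline, the fold rule and leaving out each array and each time point. A floor at the 25th percentile was planned but not run, since that percentile of the normalized values was -54.1 and has no logarithm.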

Results

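The data set holds expression profiles of mouse ES cells that carry or lack Srf, the gene of serum response factor, a transcription factor through which serum and the actin cytoskeleton control genes. Wild-type cells, Srf-null cells and a rescue line derived from the Srf-null cells were profiled at 0, 10, 30, 60 and 180 min of serum, on 15 arrays with 1 array per line and time. The 2% trimmed mean of the arrays ran from 350 to 1439 intensity units, with a median of 845. No pair among the 105 pairs of arrays was identical, and the highest correlation of log2 values across probe sets, which are not independent replicates, was 0.952.

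Srf itself had 0 probe sets in the annotation used, so the genotype labels could not be checked by the targeted gene. Other transcripts set some 0 min arrays apart from the rest of their line. Igf2, which encodes a fetal growth factor, lay below 0 on the array labelled wild-type 0 min and between 2640 and 5223 normalized intensity units on the other wild-type arrays. It lay below 0 on the array labelled rescue 0 min and between 5942 and 10240 on the other rescue arrays, and all 5 Srf-null arrays were below 0. Actg1 (cytoplasmic gamma-actin) gave 9783 and 8891 on those arrays, against 27390 to 41633 on the other wild-type and rescue arrays and 7327 to 14004 in Srf-null cells. The Y-linked gene Eif2s3y gave 134 on the array labelled wild-type 0 min and 1435 to 2078 on the other wild-type arrays. The array labelled rescue 0 min correlated best with Srf-null 180 min (r = 0.939 across probe sets) and less with its own line (highest r = 0.915), while wild-type 0 min correlated best with wild-type 30 min (r = 0.867). Nearness to another line was not limited to 0 min, since rescue 10 min correlated best with Srf-null 30 min (r = 0.943, as high as within its own line) and wild-type 30 min with Srf-null 10 min (r = 0.944).

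RNA and array quality also differed. The ratio of the 3' to the 5' control probe set of beta-actin, which rises as RNA degrades, was 7.53 on wild-type 0 min, 4.22 on rescue 0 min, 3.83 on Srf-null 60 min and 2.94 on Srf-null 0 min. It was 0.847 to 2.11 on the other 11 arrays. The same ratio for the Gapdh control was 1.51 on wild-type 0 min, 1.27 on Srf-null 0 min and 1.23 on wild-type 180 min. On rescue 0 min (0.722) and Srf-null 60 min (0.785) it lay within the range of the remaining arrays, 0.683 to 0.841. The 2 controls therefore differ on whether RNA of rescue 0 min was degraded. Srf-null 0 min was also the dimmest array, with a trimmed mean of 57.8 before a scale factor of 6.06. That factor was inferred from the spacing of the low values on the array, since the scaling is not given. The share of values at or below 0 was 37.1% to 41.6% on 5 arrays (Srf-null 30, 60 and 180 min, rescue 0 and 10 min) and 24.9% to 30.9% on the other 10. The nearest array of rescue 0 min and that of rescue 10 min lay among the same 5 arrays. The signal of the 18S ribosomal RNA control probe set was 14100 to 29300 on 7 arrays and 226 to 5560 on 8, with both kinds in each line.

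The comparison of Srf-null cells with both other lines asked which transcripts depend on the Srf genotype over the whole time course. Over all 15 arrays, Igf2 fell by 4.92 ± 0.73 on the log2 scale (SE, 5 arrays per line), although it lay below 0 on every 0 min array. Transcripts of the simple-epithelial keratin Krt8 (-2.0 ± 0.34), the trophoblast transcription factor Tfap2c (-2.98 ± 0.50) and the membrane-binding protein Anxa1 (-2.76 ± 0.39) were also lower in Srf-null cells. So were the metallothionein Mt1 (-1.64 ± 0.25), the DNA repair gene Rad50 (-1.60 ± 0.21), the DNA methyltransferase gene Dnmt3a (-1.44 ± 0.23) and the kinase gene Jak3 (-1.22 ± 0.15). The homeobox gene Nkx6-2 (2.34 ± 0.32), Lgals3 (galectin-3, 1.42 ± 0.15) and Bmp4 (bone morphogenetic protein 4, 0.85 ± 0.14) were higher. In limma's test these were the 11 named genes among 13 called probe sets, 3 higher and 10 lower, with adjusted p from 0.00525 to 0.0457. Actg1 (-1.2 ± 0.25, adjusted p = 0.106) was not called. Without the 0 min arrays Mt1 (-1.44 ± 0.28, adjusted p = 0.0568) lost its call. The 13 calls became 66 without Srf-null 0 min, 52 without rescue 0 min, 16 without wild-type 0 min and 3 to 9 without any other single array, and 0 without all arrays of 10, 30 or 60 min.

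The same comparison without the 0 min arrays gave 48 higher and 63 lower probe sets, with 4 arrays per line. Igf2 fell by 6.15 ± 0.15 (adjusted p = 4.77e-07), a lower limit since all Srf-null arrays lay at the floor. Other large falls were the keratin Krt18 (-3.45 ± 0.20), Plac8 (-3.17 ± 0.33), Cnn2 (calponin 2, an actin-binding protein, -3.06 ± 0.26), Anxa1 (-3.01 ± 0.41), Dppa3 (a germ-line and pluripotency gene, -2.79 ± 0.32), Sh3bgrl (-2.69 ± 0.25) and the kinase gene Akt1 (-2.52 ± 0.31). Higher in Srf-null cells were Mapt (the microtubule-associated protein tau, 2.90 ± 0.42), the Ras-family gene Mras (2.32 ± 0.21), Nkx6-2 (2.32 ± 0.25), Uvrag (2.27 ± 0.28), Klrb1b (1.75 ± 0.27), Spink1 (1.70 ± 0.27), Krt17 (1.66 ± 0.26) and Plaur (the urokinase receptor, 1.64 ± 0.26). Mras, Nkx6-2 and Krt17 were also lower in rescue than in wild-type cells (-3.59, -2.84 and -2.60). Their rises against both lines therefore rest largely on low values in the rescue line. Actg1 fell by 1.58 ± 0.16 (adjusted p = 0.00377), from 30790 and 36770 intensity units in wild-type and rescue cells to 11280 (geometric means of 4 arrays). The smooth-muscle actin gene Acta2 gave -1.68 ± 0.23 (adjusted p = 0.0157) but was not called, since it was above the floor in the wild-type line only and differed by 0 between rescue and Srf-null cells.

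**Figure D1:**
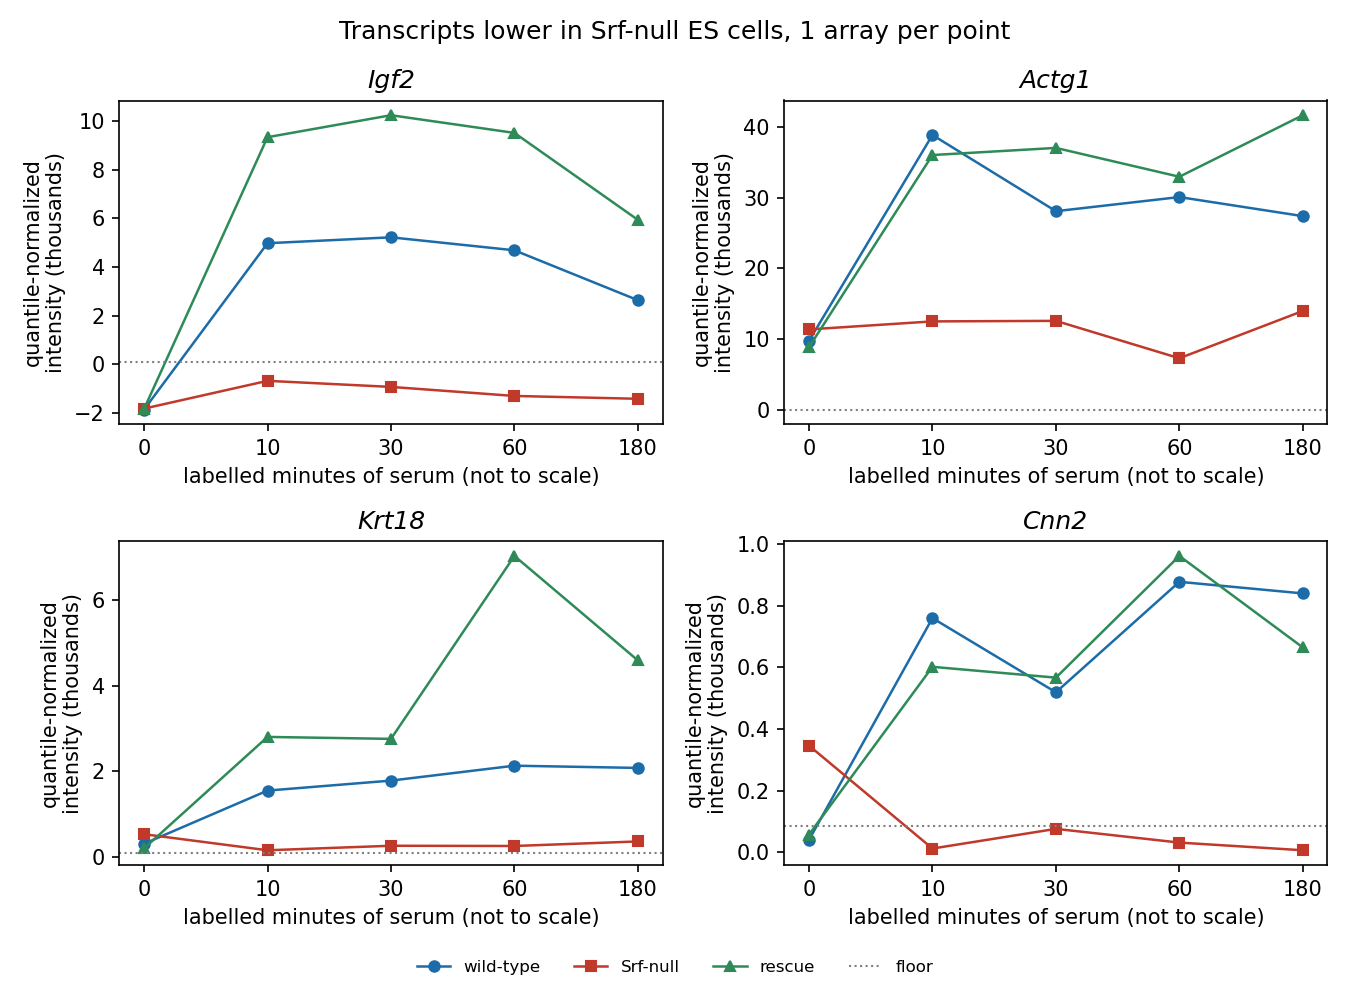
Quantile-normalized intensity (divided by 1000) of Igf2, Actg1, Krt18 and Cnn2 against the labelled minutes of serum, with 1 array per point, lines joining the arrays of a cell line, and the floor dotted. From 10 min on the Srf-null arrays lie below the wild-type and rescue arrays in each panel, Actg1 at 7327 to 14004 against 27390 to 41633, and the arrays labelled wild-type 0 min and rescue 0 min lie near the Srf-null level.

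The list of actin cytoskeleton genes that SRF and MRTF control passed camera with lower values in Srf-null cells, but not with an estimated correlation. Of 35 measured members, 0 were called over all 15 arrays in limma's test over all genes, where 1001 of the 9558 probe sets had an unadjusted p under 0.05, and 9 fell when adjusted over the list alone (median -0.20). Camera's adjusted p for the list was 0.000279, against an adjusted p of 0.395 with an estimated correlation. In the 12 arrays from 10 min on, the median was -0.35, against 0.10 when arrays were scaled to a common median, where the median of all genes was 0.37. Of the members, 8 fell over all genes (Cnn2, Actg1, Csrp1, Gsn, Tpm4, Actc1, Acta1 and Lima1), and 13 fell and 0 rose adjusted over the list alone. The list had an adjusted p of 5.29e-07 in camera and of 0.0572 with an estimated correlation. Vcl (vinculin, -0.83 ± 0.20, adjusted p = 0.102) and Tagln (transgelin, -2.44 ± 0.57, adjusted p = 0.0923) were not called over all probe sets, nor was Actb (beta-actin, -0.37 ± 0.42). Zyx (zyxin) was not above the floor often enough to be tested, and Tpm1 had no probe set.

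Immediate-early genes, which respond to serum within minutes, had a median of -0.42 over all 15 arrays, with 0 of 32 members called over all genes and 7 lower adjusted over the list alone (camera adjusted p = 0.00185, adjusted p = 0.645 with an estimated correlation). From 10 min on 5 fell over all genes (Rhob, Atf3, Btg2, Egr1 and Ccn1) and Plaur rose, while 9 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.38 with an estimated correlation). In the test over all probe sets Egr1 (-3.80 ± 0.72, adjusted p = 0.0515) and Ccn1 (-2.35 ± 0.49, adjusted p = 0.0637) were just above the threshold, and Myc gave 1.07 ± 0.32 (adjusted p = 0.171). Fos (-0.02 ± 0.39), Fosb (-0.85 ± 0.32), Junb (-0.77 ± 0.49), Fhl2 (-0.24 ± 0.24) and Bcl2 (-0.72 ± 0.65) were not called.

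The pluripotency list passed camera with slightly higher values in Srf-null cells, but not with an estimated correlation. Over all 15 arrays 21 of 23 members had a positive change (median 0.34), 0 were called over all genes, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000279, adjusted p = 0.395 with an estimated correlation). From 10 min on Tbx3 (1.14 ± 0.13), Nr0b1 (0.57 ± 0.11) and Fgf4 (0.45 ± 0.09) rose and Dppa3 fell over all genes, with 7 higher and 1 lower adjusted over the list alone. That list had an adjusted p of 0.000381 in camera and of 0.073 with an estimated correlation. With arrays scaled to a common median its median of 0.34 became 0.59 over all 15 arrays and that of 0.30 became 0.81 from 10 min on, where all genes had 0.18 and 0.37. Of 18 imprinted genes, Igf2, Mest (-0.95 ± 0.16) and Ndn (-1.24 ± 0.24) fell over all genes. Further, 8 fell and 2 rose adjusted over the list alone (adjusted p = 0.0006 in camera and adjusted p = 0.126 with an estimated correlation). Of 11 trophoblast genes, 3 fell by both adjustments, Krt18, Krt8 (-2.41 ± 0.16) and Tfap2c (-3.29 ± 0.55), the keratins being found in other simple epithelia too (adjusted p = 0.00567 in camera and adjusted p = 0.139 with an estimated correlation).

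These line calls depended on the 0 min arrays and on the technical splits. With the share of non-positive values as a term beside line and time, and no 0 min arrays, 7 of the 111 calls were left. Among them were Igf2 (-6.20, adjusted p = 4.99e-05), Krt18 (-3.52, adjusted p = 0.0123) and Cnn2 (-2.98, adjusted p = 0.0498), whereas Actg1 gave -1.5 ± 0.21 (adjusted p = 0.0829). All 111 kept their direction, with a median size of 0.973 times that without the term, and the spread was wider with 1 degree of freedom less and a term that overlaps the Srf-null line. With the 18S split as the term instead, 82 were higher and 103 lower, 110 of the 111 among them, and Egr1 (-3.93 ± 0.68, adjusted p = 0.0385) and Vcl (-0.78 ± 0.14, adjusted p = 0.0394) were then called. With both terms 1 call was left, and again all 111 kept their direction. Between single arrays on the same side of the split by non-positive values, Srf-null against wild-type at 10 min, Igf2 differed by -5.87, Krt18 by -3.31, Cnn2 by -3.16 and Actg1 by -1.63. Over 0 and 10 min together, which takes in the 0 min arrays with Igf2 below 0, the means were -2.94, -1.26, -0.57 and -0.71. Over both times Dppa3 (0.05), Mras (-0.96) and Plaur (-0.43) had the other direction than their calls from 10 min on, and Laptm5 (-0.18) than its call against wild-type cells. So did Egr1 (0.50), called lower in the fit over genes and with the 18S term, and Vcl (0.22), called lower with the 18S term. On the other side, Srf-null 30, 60 and 180 min against rescue 10 min, the differences were -6.78, -3.27, -2.82 and -1.73.

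The other lists did not pass camera for Srf-null against both lines without the 0 min arrays. Their medians and adjusted p were -0.06 and 0.126 for 23 extracellular matrix and adhesion genes (1 up and 3 down over all genes, 1 up and 7 down adjusted over the list alone), -0.20 and 0.0558 for 18 endoderm genes, -0.05 and 0.349 for 11 interferon response genes, and -0.05 and 0.384 for 15 cholesterol synthesis genes. Cell-cycle genes of G1 and S phase (18 genes, adjusted p = 0.729) and of G2 and mitosis (15 genes, adjusted p = 0.654), apoptosis regulators (14 genes, adjusted p = 0.901), p53 targets (8 genes, adjusted p = 0.81) and hypoxia and glycolysis genes (17 genes, adjusted p = 0.654) did not pass. Neither did ribosomal proteins (14 genes, adjusted p = 0.898), heat shock and unfolded protein genes (18 genes, adjusted p = 0.823) and BMP and TGF-beta targets (9 genes, adjusted p = 0.894). The same held for mesoderm (8 genes, adjusted p = 0.957), ectoderm and neural (9 genes, adjusted p = 1), fibroblast feeder genes (15 genes, adjusted p = 0.901) and the X and Y label check (3 genes, adjusted p = 0.0974). In all, 25 of 231 planned list tests over the 15 arrays and 22 of 84 without the 0 min arrays passed camera, and 0 of either with an estimated correlation.

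The comparison of Srf-null with wild-type cells alone gave 0 higher and 0 lower probe sets over all 15 arrays in limma's test, with 916 at an unadjusted p under 0.05. From 10 min on 10 were higher and 21 lower. Falls included Igf2 (-5.64 ± 0.17), Acta2 (-3.37 ± 0.27), Eif2s3y (-3.26 ± 0.29), Cnn2 (-3.11 ± 0.29), Anxa1 (-3.06 ± 0.47), Krt18 (-2.91 ± 0.23), Plac8 (-2.65 ± 0.38), Dppa3 (-2.59 ± 0.37) and Actg1 (-1.45 ± 0.18). Rises were Uvrag (2.43 ± 0.33), Piga (1.31 ± 0.16), Rpl39l (1.27 ± 0.19), Lgals3 (1.25 ± 0.14), the glycolytic enzyme gene Pfkp (1.08 ± 0.16), Tmem223 (0.82 ± 0.13) and Laptm5 (0.71 ± 0.09). The actin list had a median of -0.38 (0.12 with arrays scaled to a common median, where all genes had 0.44). Of its 35 members 4 fell over all genes and 14 adjusted over the list alone (camera adjusted p = 1.01e-07, adjusted p = 0.0572 with an estimated correlation). Of the 17 hypoxia and glycolysis genes, 1 rose over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0153, adjusted p = 0.38 with an estimated correlation). Camera also passed the immediate-early list (median -0.35, 0.13 with a common median, adjusted p = 0.00256), pluripotency (0.23, adjusted p = 0.0234), imprinted genes (-0.42, adjusted p = 0.00507) and the X and Y label check (-0.30, adjusted p = 0.0106), where Eif2s3y was the member called. With an estimated correlation these 4 did not pass (adjusted p of 0.307, 0.139, 0.149 and 0.139). With the share of non-positive values as a term 1 call was left, although all 31 kept their direction at a median of 0.955 times their size. With the 18S split there were 29, of which 24 were shared with the 31.

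The comparison of rescue with Srf-null cells asked which transcripts changed with the rescue, which need not be a return to the wild-type level. Over all 15 arrays 11 probe sets were higher and 10 lower in rescue cells. The rises included Tfap2c (4.27 ± 0.58), Calcoco2 (2.73 ± 0.48), Anxa1 (2.72 ± 0.45), Mt1 (2.05 ± 0.29), Rad50 (1.83 ± 0.24), Jak3 (1.70 ± 0.18), Dnmt3a (1.70 ± 0.27) and the stress-response gene Ddit4 (1.25 ± 0.22). The falls included Nkx6-2 (-3.62 ± 0.36), the homeobox gene Gbx2 (-2.72 ± 0.37), Krt17 (-2.63 ± 0.41), Bmp4 (-1.81 ± 0.32), Lgals3 (-1.75 ± 0.17), Emp1 (-1.33 ± 0.19), Atp2a3 (-1.18 ± 0.21) and Fgf4 (-0.68 ± 0.11). Bmp4 was read here by another probe set than in Srf-null against both lines. The 21 calls became 103 without rescue 0 min, 90 without Srf-null 0 min, 48 without wild-type 0 min and 4 to 18 without any other single array. From 10 min on 112 were higher and 103 lower. Igf2 rose by at least 6.66 ± 0.17, Krt18 by 4.0 ± 0.23, the neural transcription factor gene Sox3 by 3.96 ± 0.39, Plac8 by 3.69 ± 0.38, Cnn2 by 3.01 ± 0.29, Krt19 by 2.99 ± 0.42, Dppa3 by 2.99 ± 0.37 and Actg1 by 1.71 ± 0.18. Mras (-4.12 ± 0.25), Mapt (-3.34 ± 0.48), Defa23 (-2.52 ± 0.40), Rab31 (-2.38 ± 0.35) and the non-muscle myosin gene Myh9 (-2.37 ± 0.44) were lower. Sox3 (3.97), Mras (-3.59) and Myh9 (-3.01), among others, differed in the same direction from wild-type cells, whereas Actg1 (0.26) was not called there. The changes of Sox3, Mras and Myh9 are therefore not a return to the wild-type level. The Sox3 probe set with the highest mean gave a smaller difference, -1.74 for Srf-null 30, 60 and 180 min against rescue 10 min.

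Without the 0 min arrays the actin list had a median of 0.21 in rescue against Srf-null cells, and of -0.10 with arrays scaled to a common median, where all genes had -0.28. There were 6 of 35 members up and 1 down over all genes and 11 up and 2 down adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.073 with an estimated correlation). Pluripotency genes passed camera with lower values, with 4 of 23 down and 1 up over all genes and 6 down and 1 up adjusted over the list alone (camera adjusted p = 8.17e-05, adjusted p = 0.0582 with an estimated correlation). Trophoblast genes (3 of 11 up over all genes, 4 adjusted over the list alone, camera adjusted p = 0.000163) and primitive and visceral endoderm genes (3 of 18 up over all genes, 4 adjusted over the list alone, camera adjusted p = 0.00632) passed camera with higher values. They did not pass with an estimated correlation (adjusted p of 0.0786 and 0.149), and the endoderm median of 0.39 became -0.02 with arrays scaled to a common median. Imprinted genes passed camera with higher values too (6 of 18 up and 1 down over all genes, 7 up and 2 down adjusted over the list alone, camera adjusted p = 0.000731, adjusted p = 0.126 with an estimated correlation). Egr1 gave 3.80 ± 0.83 (adjusted p = 0.0621) and was not called. With the share of non-positive values as a term 61 of the 215 calls were left, although all 215 kept their direction at a median of 0.983 times their size. With the 18S split there were 263, of which 195 were shared with the 215.

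The comparison of rescue with wild-type cells asked how far the rescue line differed from the line with normal Srf. It gave 0 higher and 0 lower probe sets over all 15 arrays in limma's test, with 693 at an unadjusted p under 0.05, and 13 higher and 25 lower without the 0 min arrays. Lower in rescue cells were Mras (-3.59 ± 0.25), Acta2 (-3.37 ± 0.27), Myh9 (-3.01 ± 0.44), Nkx6-2 (-2.84 ± 0.28), Krt17 (-2.60 ± 0.30), Eif2s3y (-2.13 ± 0.29), Emp1 (-1.41 ± 0.18) and Kdelr3 (-1.33 ± 0.19). Higher were Sox3 (3.97 ± 0.39), Esx1 (2.50 ± 0.38), Abcd4 (2.43 ± 0.38), the imprinted gene Peg3 (1.77 ± 0.26), Crabp1 (1.74 ± 0.20), Dab2 (1.69 ± 0.20), Cd276 (1.45 ± 0.19) and Ak4 (1.32 ± 0.17). The Sox3 probe set with the highest mean gave a smaller difference, 1.78 over 30, 60 and 180 min. Of the 17 hypoxia and glycolysis genes 2 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000495, adjusted p = 0.215 with an estimated correlation). Of 11 trophoblast genes 1 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000509, adjusted p = 0.0994 with an estimated correlation). Camera also passed the X and Y label check (median -0.30, adjusted p = 0.00887, with Eif2s3y called), pluripotency (-0.19, adjusted p = 0.00632), endoderm (0.34, adjusted p = 0.00777) and p53 targets (0.43, adjusted p = 0.00632). With an estimated correlation these 4 did not pass (adjusted p of 0.139, 0.123, 0.157 and 0.258). Egr1 (-0.01 ± 0.83) and Actg1 (0.26 ± 0.18) were not called. With the share of non-positive values as a term 12 calls were left, although all 38 kept their direction at a median of 0.987 times their size.

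The early serum response, 30 and 60 min against 0 and 10 min, averaged over the lines, gave 0 calls in limma's test, with 243 probe sets at an unadjusted p under 0.05. Egr1, an immediate-early transcription factor gene, had a mean change of 2.41 ± 0.79 (6 early and 6 baseline arrays, adjusted p = 0.995). The immediate-early list had a median of 0.41, with 25 of 32 members positive and 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.688 with an estimated correlation). The 0 calls within wild-type and within rescue cells stood beside 243 and 380 probe sets at an unadjusted p under 0.05. In Srf-null cells 4 rose and 3 fell, the rises including the cyclin gene Ccne1 (4.89 ± 0.52), Pnliprp2 (1.82 ± 0.21) and Atp6v0a1 (1.48 ± 0.19), and the falls Efnb3 (-3.60 ± 0.47), the keratin gene Krt1 (-3.47 ± 0.33) and H2-DMa (-1.97 ± 0.23). With the 18S split as a term these 6 kept their size (Ccne1 4.75 ± 0.58, adjusted p = 0.109) and 0 calls were left, with 1 residual degree of freedom less. In Srf-null cells both arrays of 0 and 10 min lay on one side of the split by non-positive values and both of 30 and 60 min on the other, so within this line alone the early response of these genes is confounded with that split.

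The late response, 180 min against 0 and 10 min, gave 5 rises and 0 falls. They included the immediate-early genes Egr1, by its dimmer probe set (2.67 ± 0.34, adjusted p = 0.0488), and Fosl1 (1.17 ± 0.13, adjusted p = 0.0308), and the non-coding transcript Gt(ROSA)26Sor (1.36 ± 0.14, adjusted p = 0.0219), which rests mostly on Srf-null 180 min, with 2 unnamed probe sets. The 3 named ones lay near or below the floor on most arrays at 0 to 60 min. The immediate-early list had a median of 1.18 with 30 of 32 members positive, 0 called over all genes and 15 higher adjusted over the list alone (camera adjusted p = 1.11e-20, adjusted p = 0.395 with an estimated correlation). BMP and TGF-beta targets had a median of 0.50 with 0 of 9 called by either adjustment (camera adjusted p = 0.0089, adjusted p = 0.395 with an estimated correlation). Either technical split as a term left 0 late calls.

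The comparison of 60 and 180 min with 10 and 30 min leaves out the 0 min arrays and was chosen after results had been seen. It gave 13 calls, against 0 and 5 for the planned early and late response. In 5 of 100 regroupings of the arrays, the true one included, there were at least as many. Averaged over the lines, transcripts of the activating transcription factor gene Atf3 (2.41 ± 0.30), the mRNA decay factor gene Zfp36 (2.34 ± 0.18), and the BMP target Id1 (2.32 ± 0.28) rose. So did the small GTPase gene Rhob (1.76 ± 0.13), the MAP kinase phosphatase gene Dusp1 (1.72 ± 0.19), Fosb (1.43 ± 0.07) and Ier2 (1.32 ± 0.17). Snhg5 (1.10 ± 0.11), the metallothionein Mt2 (1.10 ± 0.14) and Epc1 (0.81 ± 0.11) rose and Rhbdl3 fell (-2.46 ± 0.22), among 12 rises and 1 fall in limma's test (6 arrays against 6). Egr1 gave 2.37 ± 0.33 (adjusted p = 0.0562) and was called with the 18S split as a term (2.21 ± 0.17, adjusted p = 0.00928). Of the 32 immediate-early genes 30 had a positive change (median 1.14), 8 rose over all genes and 20 rose adjusted over the list alone, with an adjusted p of 6.61e-32 in camera and of 0.0471 with an estimated correlation. Of 9 BMP and TGF-beta targets 1 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.295 with an estimated correlation). With the share of non-positive values as a term 8 calls were left. The 13 calls became 220 without wild-type 60 min, 184 without Srf-null 180 min, 57 without Srf-null 60 min, 25 without rescue 180 min and 6 to 15 without any other single array.

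Within wild-type cells Zfp36 (3.40 ± 0.32), Fosb (2.21 ± 0.12) and Nell2 (2.11 ± 0.22) rose. There 2 of the 32 immediate-early genes rose over all genes and 18 adjusted over the list alone (camera adjusted p = 4.16e-28, adjusted p = 0.0471 with an estimated correlation). Within rescue cells Klf13 (2.34 ± 0.18), Rhob (2.06 ± 0.23) and Fosb (1.86 ± 0.12) rose and Ccdc86 fell (-1.76 ± 0.16). There 2 immediate-early genes rose over all genes and 12 adjusted over the list alone (camera adjusted p = 5.08e-20, adjusted p = 0.0772 with an estimated correlation). Within Srf-null cells 8 rose, named ones being Tpgs1 (2.24 ± 0.20), Ifitm10 (1.98 ± 0.20), Prl (1.86 ± 0.20), Evi2a (1.71 ± 0.16), Foxf1 (1.5 ± 0.16), Crat (1.47 ± 0.15) and Klhdc4 (1.06 ± 0.13). There 4 immediate-early genes rose adjusted over the list alone and 0 over all genes (median 0.55, camera adjusted p = 1.05e-11, adjusted p = 0.215 with an estimated correlation).

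**Figure D2:**
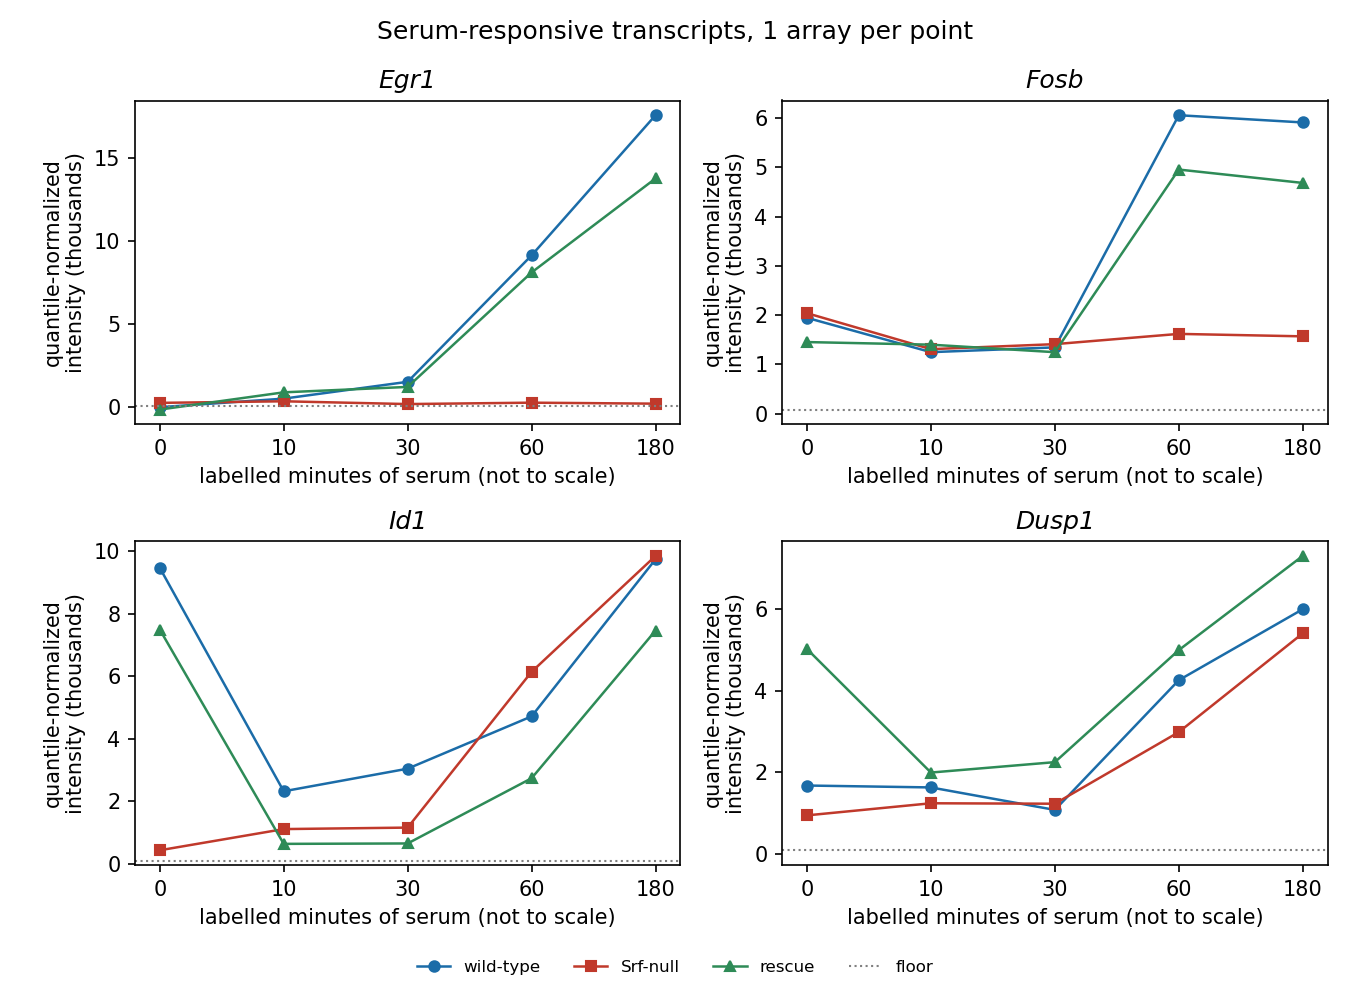
Quantile-normalized intensity (divided by 1000) of Egr1, Fosb, Id1 and Dusp1 against the labelled minutes of serum, with 1 array per point, lines joining the arrays of a cell line, and the floor dotted. Egr1 reaches 17551 in wild-type and 13748 in rescue cells at 180 min and stays at 343 or below in Srf-null cells, Fosb differs likewise at 60 and 180 min, and Id1 and Dusp1 are higher at 180 than at 10 min in all 3 lines.

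Whether the serum response differs by Srf genotype was tested as the difference between the response of Srf-null cells and the mean response of both other lines. From 10 and 30 to 60 and 180 min the rise of Fosb was smaller in Srf-null cells by 1.81 ± 0.14 log2 units (adjusted p = 0.0105), with 0.23 ± 0.12 in Srf-null, 2.21 ± 0.12 in wild-type and 1.86 ± 0.12 in rescue cells. Tpgs1 (2.24 ± 0.25), Ifitm10 (2.10 ± 0.24) and Evi2a (1.75 ± 0.20) rose more in Srf-null cells, which made 3 higher and 1 lower in limma's test. These 3 were called in 7, 8 and 7 of 15 fits with 1 array left out and lost their calls with either technical split and with a common trimmed mean. With the floor at the 55th percentile Tpgs1 gave 0.302 ± 0.175. Egr1 differed by -3.71 ± 0.71 and was not called (adjusted p = 0.435). Its signal went from 503 to 17551 in wild-type and from 882 to 13748 in rescue cells between 10 and 180 min and stayed between 176 and 343 in Srf-null cells. The immediate-early list had a median difference of -0.32 (0.19 with arrays scaled to a common median, where all genes had 0.45). It had 1 of 32 members lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000686, adjusted p = 0.378 with an estimated correlation). Fosb kept its call with the 18S split as a term (-1.81 ± 0.14, adjusted p = 0.0255), and with the share of non-positive values it gave -1.91 ± 0.17 (adjusted p = 0.0697). It was not called without rescue 60 min (-1.78 ± 0.15), without rescue 180 min (-1.82 ± 0.14), with a common trimmed mean (-1.68 ± 0.17) or with a common median (-1.19 ± 0.38).

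The planned difference in early response called Ccne1 (6.39 ± 0.63, adjusted p = 0.0181), which rose in Srf-null cells against -1.68 and -1.32 in wild-type and rescue cells, and Krt1 (-3.93 ± 0.40, adjusted p = 0.0181). Egr1 differed by -4.29 ± 1.68 (adjusted p = 0.514). With 1 array left out in turn, Ccne1 gave 6.08 to 6.69 and was called in 7 of 15 fits, and Krt1 gave -4.25 to -3.62 and was called in 8. Both calls ended without wild-type 0, 30 or 60 min, Srf-null 0 min (adjusted p of 0.0734 and 0.053), or rescue 0, 30 or 60 min. They also ended with the 18S split (adjusted p = 0.0971 for both) and with the floor at the 55th percentile (4.446 ± 0.629 and -2.723 ± 0.42). Over all settings Ccne1 ranged from 4.446 to 7.388 and Krt1 from -4.62 to -2.723, and with time as an added term Krt1 (-3.934 ± 0.424) was not called. The difference in late response called Gt(ROSA)26Sor (3.23 ± 0.29, adjusted p = 0.0141), which rests on a single array, Srf-null 180 min at 972 units, against values at or below 126 on the other 14, and which was not called with time as an added term (3.233 ± 0.349). Among the lists only ribosomal protein genes passed for that difference (median -1.09, 0 of 14 called by either adjustment, camera adjusted p = 0.00899, adjusted p = 0.688 with an estimated correlation). Its median depended on scaling (-1.57 with a common median and -2.36 with a common trimmed mean), and the 18S signal was higher at 180 than at 0 and 10 min in wild-type cells and lower in Srf-null cells.

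By size alone, 1930 of the 9558 probe sets in wild-type, 2193 in Srf-null and 1531 in rescue cells reached at least 2 times their 0 min signal at 30 or 60 min. Of these 472 were shared by wild-type and rescue cells, where 309 would be shared by independent lists, and 154 by all 3 lines. Numbers for independent lists count all 9558 probe sets, also those at the floor in both lines, and the 0 min arrays of both lines are doubted. An excess over them therefore does not by itself show a shared serum response. With the 10 min array as the start the counts were 1165, 1456 and 1066, with 281 shared by wild-type and rescue cells against 130 for independent lists. The median of the 32 immediate-early genes against 10 min was 1.13 at 60 min and 1.54 at 180 min in wild-type, 0.77 and 1.36 in rescue, and 0.31 and 0.81 in Srf-null cells, each at or above the 99.9th percentile of matched random lists. Against 0 min the rescue medians at 10 and 30 min were -0.50 and -0.53, at the lowest percentile (0).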

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

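Of the tests in this part, leaving out Srf-null 0 min was set before its result was seen, and those with the technical splits and the starting level of Fosb were chosen after. The rule that marked these genes was a called difference between Srf-null cells and both other lines in the same response.

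The early response of Ccne1 was higher in Srf-null cells than in both other lines by 6.39 ± 0.63, and that of Krt1 was lower (-3.93 ± 0.40, adjusted p = 0.0181 for both). The low signal of Srf-null 0 min is argued against as the whole cause, since without that array both kept at least 0.919 of their size (6.39 ± 0.78 and -3.62 ± 0.33), although both calls ended with 1 degree of freedom less and, for Ccne1, a wider spread (adjusted p of 0.0734 and 0.053). The 18S split is argued against too, with at least 0.978 of the size kept (6.25 ± 0.69 and -3.94 ± 0.445), where wider spread and 1 degree of freedom less again ended both calls (adjusted p = 0.0971). The split by non-positive values, which parts rescue arrays the opposite way, predicts a shift of rescue against wild-type cells, and Ccne1 gave 0.369 ± 0.73 against 6.57 in Srf-null cells, while Krt1 gave 1.43 ± 0.46, so that this split may explain part of Krt1. A biological difference in early response remains open as untested, since each line is a single series and Ccne1 was called in 7 of 15 fits with 1 array left out. With the floor at the 55th percentile neither was called (4.446 ± 0.629 and -2.723 ± 0.42), nor was Krt1 with time as an added term (-3.934 ± 0.424).

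Fosb rose less in Srf-null cells between 10 and 30 and 60 and 180 min (-1.81 ± 0.14, adjusted p = 0.0105), and Egr1 had the same direction without a call (-3.71 ± 0.71). A higher starting level is argued against, since Fosb differed by 0.054 at 10 and 30 min. With the 18S split as a term 1.002 of the Fosb difference was kept and the call stayed, and with the split by non-positive values 1.057 was kept (-1.91 ± 0.17), although the wider spread and 1 degree of freedom less ended the call (adjusted p = 0.0697). The common median scaling left -1.19 ± 0.38 without a call. The Srf genotype and any other difference between the lines stay open as untested, with 1 series per line and 0 probe sets for Srf.

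In 60 and 180 against 10 and 30 min, Tpgs1 (2.24 ± 0.25), Ifitm10 (2.10 ± 0.24) and Evi2a (1.75 ± 0.20) rose more in Srf-null cells, each with an adjusted p of 0.0463. Wider spread and 1 degree of freedom less ended these calls with the 18S split (2.22 ± 0.26, 2.08 ± 0.26 and 1.759 ± 0.215, adjusted p = 0.12) and with the split by non-positive values (2.24 ± 0.30, 2.10 ± 0.29 and 1.645 ± 0.229). Smaller size and wider spread ended them with a common trimmed mean (2.0 ± 0.27, 1.89 ± 0.31 and 1.18 ± 0.25). With 1 array left out they were called in 7, 8 and 7 of 15 fits. Tpgs1 was above the floor on 2 arrays, Srf-null 60 and 180 min, and gave 0.302 ± 0.175 with the floor at the 55th percentile. In the late response Gt(ROSA)26Sor differed by 3.23 ± 0.29 through a single bright array. The 18S ribosomal RNA control probe set, which entered no planned comparison, differed 129.5-fold between the highest and the lowest array.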

How the results depend on the processing

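The single-array design limits every result here, since a line has 1 array per time and a 0 min array that is dim, degraded or doubted enters each baseline. Settings without the 2 doubted arrays, with technical splits, and for 60 and 180 against 10 and 30 min were chosen after seeing the data. In these settings no single gene reversed its direction after a call, while medians of some lists that passed camera changed sign with a common median (the actin list from -0.35 to 0.10 in Srf-null against both lines without the 0 min arrays). Among single genes, 2015 values in other settings and 3580 with arrays left out kept their call or stayed uncalled within 1 standard error, 202 and 386 lost their call, 28 and 24 gained one, and 208 and 202 moved by more than their standard error or gained a call in the other direction. The cause was not tested unless given.

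Scaled to a common median, the median of all probe sets became 0.778 for the early difference, 0.616 for the late difference, 0.387 for the difference in 60 and 180 against 10 and 30 min, 0.553 for the early Srf-null response, -0.488 for the early rescue response, and 0.165, 0.249 and 0.157 for Srf-null against both lines, Srf-null against wild-type and rescue against wild-type. With a common trimmed mean it was -0.113 for the late difference. Calls with a common median were 2 for Srf-null against both lines, 6 for rescue against Srf-null, 941 for the early difference (through the shift of all probe sets), 3 for 60 and 180 against 10 and 30 min and 1 for its difference. That setting gave 4544 probe sets in Srf-null cells with a 2-fold rise, 45 lists past camera, and an adjusted p of 0.112 for the immediate-early list in that difference. A common trimmed mean gave 1 call for Srf-null against wild-type, 6 for the early difference and 0 for the difference in 60 and 180 against 10 and 30 min.

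With the floor at the 55th percentile, rescue against Srf-null had 39 calls, rescue against wild-type 1, the early Srf-null response 0, the early difference 0, 60 and 180 against 10 and 30 min 20 and its difference 1, with 1034, 944 and 656 risers in wild-type, Srf-null and rescue cells. With probe sets above the floor on 5 arrays, rescue against Srf-null had 38 calls, rescue against wild-type 2, the late mean 0, the early Srf-null response 2, the early difference 5, the late difference 0, 60 and 180 against 10 and 30 min 20 and its difference 1. With no filter, Srf-null and rescue against wild-type each had 2 calls, the early and late mean 15 and 233, the early response 3, 25 and 10 in wild-type, Srf-null and rescue cells, the early and late difference 40 and 248, and 60 and 180 against 10 and 30 min 24 with 18 for its difference. With no intensity trend, rescue against wild-type had 2, the late mean 0, the early wild-type response 2, the early Srf-null response 25, the early difference 41 and 60 and 180 against 10 and 30 min 6.

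With no time term, Srf-null against both lines had 1 call, rescue against Srf-null 12 and rescue against wild-type 3, and from 0 and 10 min alone Srf-null against both lines and rescue against Srf-null had 0. One probe set per gene gave 2 for rescue against wild-type. In an additive model of line and phase the late mean had 0. With time as an added term, the early Srf-null response had 1, the early difference 1 and the late difference 0. With 0 min alone as the baseline, the early and late mean had 767 and 463, the early response 506, 657 and 151 in wild-type, Srf-null and rescue cells, and the early and late difference 800 and 573, with few residual degrees of freedom and many values at the floor. A 1.5-fold rule gave 2951 risers in wild-type and 2593 in rescue cells, a 3-fold rule 1002, 1261 and 749, the mean of 0 and 10 min as baseline 1235 in wild-type cells, and 10 min as baseline 1165 and 1456 in wild-type and Srf-null cells. With an estimated correlation 0 of the 231 planned list tests passed, with an adjusted p of 0.395 for the actin and pluripotency lists in Srf-null against both lines and for the immediate-early list in the late mean, whereas 2 of the 105 list tests on 60 and 180 against 10 and 30 min passed, both of the immediate-early list (0.0471), which had 0.378 in the difference.

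Without wild-type 0 min and rescue 0 min, the 4 line comparisons (Srf-null against both, Srf-null against wild-type, rescue against Srf-null, rescue against wild-type) had 119, 31, 211 and 38 calls, the late mean 16, the early response 5 and 2 in wild-type and rescue cells, the early difference 0 and the late difference 2. The split by non-positive values as a term gave 6 for Srf-null against both lines, 0 for the late mean, 8 for 60 and 180 against 10 and 30 min and 0 for its difference, and without the 0 min arrays 7, 1, 61 and 12 for the line comparisons. For the late mean that fit was additive in line and phase, a model that had 0 calls without the split too. The 18S split gave 0 for the late mean, the early Srf-null response, and the early and late difference, 1 for the difference in 60 and 180 against 10 and 30 min, and without the 0 min arrays 185, 29, 263 and 43 for the line comparisons. Both splits together gave 1, 1, 53 and 25.

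With each array or each time point left out in turn, calls ranged from 0 to 111, 0 to 31, 4 to 215 and 0 to 38 for the line comparisons, each highest without the 0 min arrays. The early and late mean gave 0 to 757 and 4 to 452, the early response 0 to 503, 0 to 656 and 0 to 146 in wild-type, Srf-null and rescue cells, and the early and late difference 0 to 789 and 0 to 572, each highest without the 10 min arrays. The comparison of 60 and 180 with 10 and 30 min gave 6 to 459 and its difference 0 to 375. Risers were 1396 to 1474, 1572 to 1653 and 1089 to 1106 in wild-type, Srf-null and rescue cells, and 16 to 33 lists passed camera. Adjusted p ranged from 2.01e-07 to 0.0135 for the actin list and 2.07e-05 to 0.00607 for the pluripotency list in Srf-null against both lines. For the immediate-early list they ranged from 5.82e-23 to 0.000316 in the late mean, 6.61e-32 to 7.92e-13 in 60 and 180 against 10 and 30 min, and 5.59e-05 to 0.267 in its difference.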

Other observations

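All tests on the 0 min arrays in this part were chosen after the values had been seen, and some rules were changed after a first outcome. The counts for other splits of the arrays were set before theirs were seen, except that those between 2 lines were limited to matched times afterwards and the 18S signal was added as a term afterwards.

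The arrays labelled wild-type 0 min and rescue 0 min lay near the Srf-null line on the probe sets that differed between Srf-null cells and both lines from 10 min on (48 higher, 63 lower), scored from 0 (own line) to 1 (Srf-null line). Against an exchange of 0 min labels with the Srf-null line, Srf-null 0 min (with 0 for both other lines) scored 0.968 on the lower group. It scored only 0.451 (0.236 to 0.707) on the higher group. Wild-type 0 min and rescue 0 min scored high on the lower group too (0.899 and 0.933). A high score there marks every 0 min array and so does not settle the exchange. RNA of another line under the label remains open: rescue 0 min scored 0.774 (interval 0.537 to 0.991) and 0.933, as that explanation needs, and wild-type 0 min 0.486 (0.169 to 0.836) and 0.899, which decides nothing. The 95% intervals come from 2000 resamplings of the probe sets, which are not independent, and hold no spread between arrays. Rescue 0 min also lay on the same side of the split by non-positive values as Srf-null 30, 60 and 180 min, which can raise its score. A serum-starved state and degraded RNA could not be told apart from RNA of another line by the tests made. The rise of the 63 lower transcripts from 0 to 10 min, Igf2 among them, was not tested against starvation. From 0 to 10 min the 48 higher transcripts fell by a median of 0.376 in wild-type and 1.36 in rescue cells (at most 1 for a half-life of 10 min or more). They were called on arrays that include the 10 min ones, so part of the fall can follow from their choice, and its size decides nothing on starvation. Degradation of rescue 0 min rests on its beta-actin ratio, since its Gapdh ratio (0.722) was not raised. Of the later wild-type and rescue arrays, wild-type 180 min had the highest 3' to 5' ratio of beta-actin. It was scored on probe sets called without the 0 and 180 min arrays. These gave 0.375 (-0.109 to 0.678) on 13 higher and 0.167 (0.085 to 0.259) on 20 lower ones, which as a single array decides nothing. The intervals, the separate arrays, the choice of group for the exchange and the criteria for starvation and degradation were changed after a first run, in which wild-type 0 min at 0.486 had counted against another line for both arrays and the exchange was undecided at 0.451.

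Srf-null 10 min was scored on probe sets called without the 0 and 10 min arrays, with 0 for both other lines. It gave 0.455 (0.324 to 0.576) on 56 higher and 0.515 (0.338 to 0.680) on 52 lower ones. The array correlated best with wild-type 30 min (r = 0.944 across probe sets, which are not independent replicates).

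Other splits of the arrays, with 1 array of each time in each group, were counted for the line comparisons. For Srf-null against both lines over 15 arrays, few splits reached as many calls (13 calls, 3 of 100 splits with as many, highest other 22). Each line is a single series, however, and the doubted 0 min arrays are among the 15. Chance differences between independently made lines are therefore not excluded. From 10 min on (111 calls, 3 of 81) the count decides nothing, since 0 min arrays were doubted on the values compared. The 22 calls came from the later Srf-null arrays with rescue 0 min in place of Srf-null 0 min. The highest other of the 81, 314, came from 4 arrays with high 18S signal, and 153 came from the rescue line.

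Between 2 lines such splits number 16 over all times and 8 from 10 min on, too few for a share under 0.05. Over all times rescue against Srf-null had 21 calls (3 of 16 splits, highest other 40, from the later rescue arrays with Srf-null 0 min). A further 26 came from the split that parted these arrays exactly by their share of non-positive values, with which as a term 15 calls were found. Srf-null against wild-type (highest other 98) and rescue against wild-type (highest other 3) had 0 calls, where limma had 916 and 693 probe sets at an unadjusted p under 0.05. Every split reaches 0 calls, so their 16 of 16 splits decide nothing. In the arrays from 10 min on, rescue against Srf-null had 215 calls (1 of 8, highest other 6), rescue against wild-type 38 (1 of 8, highest other 1) and Srf-null against wild-type 31 (2 of 8, highest other 195, which parted the arrays exactly by their 18S signal). A first count that ignored the times (100 splits over all times, 35 from 10 min on) had given 3 of 100, 1 of 35 and 1 of 35 for rescue against Srf-null over all times and later and for rescue against wild-type later, and was replaced since the model matches the times.

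Splits with so many calls point to a structure of the samples by 18S signal, which by itself gave 67 calls without the 0 min arrays and 0 over all 15 arrays. With it as a term Srf-null against both lines had 185 calls and Srf-null against wild-type 29.

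For the counts of single probe sets in the serum responses chance cannot be excluded. The mean early response had 0 calls, with 243 probe sets at an unadjusted p under 0.05 in limma. Every split reaches 0 calls, so its 100 of 100 splits (highest other 10) decide nothing. The mean late response had 5 calls (50 of 100 splits, highest other 938, with the 3 arrays of 0 min in place of those of 180 min, a structure of the 0 min arrays). The comparison of 60 and 180 with 10 and 30 min had 13 calls (5 of 100 splits, highest other 219). In that other split 5 of the 6 arrays set together had a high 18S signal, a further structure, and 16 probe sets were called with the 18S split as a term.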
